A study of Homo sapiens with 16 samples.

How the data were processed

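Transcripts that were recovered with RISC from HEK 293 cells were measured by RNA sequencing in 16 libraries: 2 for each of 6 miRNAs, and for mir124-3p 1 titled as SOLiD and 3 titled as Illumina. The sequencer of the 12 libraries of the 6 miRNAs is not given in the labels used here, and they were taken to be SOLiD. The labels of all 16 name the RISC-trap method and a SOLiD kit for total RNA, and RNA was extracted with Trizol. The authors deposited 1 table of raw counts per gene, with 1 RefSeq mRNA and symbol to each of 19077 entries and 1 column to each library, and no normalisation. TopHat2 and the genome build hg19 are named in the processing notes of the labels. The version of TopHat2, the counting tool, the strand setting and the annotation release are not given in the sources used here. The values were checked to be whole numbers of at least 0, and each of the 16 columns was matched to 1 library. Total counts lay between 7612758 and 26527365. Current gene symbols came from a table of RefSeq names that matched 18560 of the entries by accession; 17043 symbols were unchanged. Positions in the genome and the transcript sequences were not used here.

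Groups were the miRNA named in each title, with the mir124-3p libraries parted by platform. The replicate numbers 1 and 2 follow the titles and were not used to pair the libraries in the main test; whether they or the numbers in the descriptions mark shared batches is not given in the sources used here. Each miRNA with 2 libraries was set against the mean of the other 5 such miRNAs, with 10 libraries in the reference, because the labels name no library without a miRNA. The mir124 Solid library was set against the mean of the 6 miRNAs, and the Illumina libraries of mir124 against the Solid library. Where a group had 1 library, that library was assumed to vary like the other groups. The comparisons, tests, gene lists and rule for naming genes were set before the data were examined.

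Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, scaling by the trimmed mean of M values, and robust quasi-likelihood F tests on group means, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. All adjusted p-values of genes in the report are from edgeR unless DESeq2 is named. The common biological coefficient of variation over the 12 libraries was 0.350. Mean CPM were scaled over the libraries of the comparison and CPM of single libraries over all 16. Errors of log2 fold changes are standard errors of the fitted contrast, taken from the test statistic, and errors of CPM are standard deviations over libraries. Log2 CPM used a prior count of 2. Shares of single libraries have 95% Wilson intervals, and the limit behind a count of 0 is 3 counts of the library total. Correlations between libraries are Pearson correlations across genes of log2 CPM less the mean of the 6 group means.

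Genes were named by rule. For each miRNA these were the 8 called genes with the largest increase and the 4 with the largest decrease, with a mean of at least 5 CPM over the libraries compared, whose libraries all lay above or below the other 10. Up to 3 called genes from each list by adjusted p were added, and for mir124 Solid up to 10 reported targets. For the platform comparison 4 in each direction were named. Genes outside the rule that the report gives as further members of a list were chosen after their values were seen.

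There were 19 fixed gene lists, of which 18 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 18 lists of a comparison. With an estimated correlation no list was called in any comparison. The lists were reported targets of mir124 (57 genes in the table) and of mir96 and mir1271 (22), the RISC and miRNA machinery (26), G1/S (36) and G2/M (30) cell-cycle genes, the Notch (30) and Wnt (35) pathways, regulators of cortical progenitors and neurogenesis (50), axon guidance (46), chromatin regulators (59), ribosomal proteins (88), ZNF genes (508), histones (74), markers of blood (16), fibroblasts and mesenchyme (12), neurons and glia (14), and liver and keratinocytes (9), and genes typical of HEK 293 (9). The reported targets were written from memory of other studies. A list of mitochondrially encoded genes matched 0 genes and was not tested. The histone pattern also took H1F0 and H1FX, which are not tied to replication. Near-identical genes share reads, and their values are uncertain.

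The steps were tested on simulated data with 200 changed genes per comparison. Of 100 genes changed 4-fold the tests recovered between 90% and 96% for the miRNAs with 2 libraries, 73% for mir124 Solid and 42% for the platforms. Of 100 changed 2-fold they recovered between 19% and 34%, 12% and 3%. Between 2.30% and 8.16% of the calls in the simulated data were false. The counts were drawn independently with the fitted spread, for the mir124 Solid library too. The rates therefore leave out effects shared between libraries and are not error rates of the calls reported here.

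Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors or upper-quartile scaling, no filter on low counts, a filter of 5 CPM in 2 libraries, a minimum fold of 2, each library left out in turn, other references, and the replicate number as a block. An odd or even block, thinning to the smallest total, a mean of at least 20 CPM and the removal of mir1301-3p were added after seeing the data. Tests of seed matches were planned and not run, as no transcript sequence was used here. For mir550-3p the description says 550a where the title gives no letter, and the values are given under the title. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.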

Results

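RNA recovered with the RNA-induced silencing complex (RISC) was sequenced from HEK 293 cells, a transformed line derived from human embryonic kidney, for 7 microRNAs (miRNAs). In the RISC-trap assay a dominant-negative form of GW182, the protein encoded by TNRC6A, holds target mRNAs on the miRNA-loaded complex so that they can be precipitated with it. The series is about miRNAs of primates and their targets in the germinal zone of the developing brain, and each comparison asks which mRNAs were recovered more with 1 miRNA than with the others. There were 16 libraries. The miRNAs mir1180-3p, mir1260a-5p, mir1271-5p, mir1301-3p, mir3613-5p and mir550-3p had 2 libraries each. For mir124-3p there was 1 library titled as SOLiD, called mir124 Solid here, and 3 titled as Illumina. The sequencer of the 12 libraries of the other miRNAs is not named in the labels used here. A SOLiD kit is named for all 16, and the 12 were taken to be SOLiD. The labels name no library without a miRNA, so the background of the assay was not measured and each value is relative to the other pulldowns.

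The count table held 19077 genes. Total counts in replicate 1 and replicate 2 were 12979758 and 9448775 for mir1180-3p, 11676390 and 11242721 for mir1260a-5p, and 17972321 and 8004955 for mir1271-5p. They were 7612758 and 8533543 for mir1301-3p, 13500185 and 11299759 for mir3613-5p, and 14491600 and 16089463 for mir550-3p. The mir124 Solid library held 12460405 counts, and the Illumina libraries held 19484899, 20473484 and 26527365. A count of 0 allowed up to 0.394 CPM (per-million counts) in the shallowest library and 0.113 in the deepest, from 3 counts of the total. Intervals and limits of this kind cover counting error alone. For the 6 miRNAs with 2 libraries these differed by far more than counting error: the chi-square per degree of freedom was between 36.7 for mir1180-3p and 84.8 for mir1260a-5p. The p-values of single genes below measure the spread between these libraries, which can be technical. Those of gene lists compare a list with the other genes at a preset correlation of 0.01 between genes. They treat genes as nearly independent and are no measure of that spread. With an estimated correlation no list was called.

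The libraries of a miRNA did not always resemble each other most. Across genes, the correlation of deviations from the mean of the 6 miRNAs was 0.60 between the mir1301-3p libraries, 0.42 between the mir550-3p libraries and 0.31 between the mir1180-3p libraries. It was 0.18 for mir3613-5p, -0.12 for mir1260a-5p and -0.13 for mir1271-5p. Of the 12 libraries, 5 correlated best with their own partner. Replicate 1 of mir1271-5p and replicate 1 of mir3613-5p correlated at 0.38, and so did replicate 2 of mir1260a-5p and replicate 2 of mir3613-5p. Genes are not independent replicates, so no p-value was attached to these correlations.

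TNRC6A itself, whose counts do not separate the endogenous gene from the GW182 construct, took between 0.665% and 1.49% of the counts in the 12 libraries (95% Wilson intervals 0.660% to 0.671% and 1.48% to 1.496%). Its share was 5.11% in the mir124 Solid library (5.10% to 5.13%). In the Illumina libraries it was 4.003% (3.99% to 4.01%), 1.07% (1.06% to 1.07%) and 3.97% (3.96% to 3.97%), so replicate 2 stood apart from replicates 1 and 3. The chi-square per degree of freedom was 7.29 between Illumina replicates 1 and 3, and 89.6 and 102 between replicate 2 and each of these.

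Upper-quartile scaling in place of the trimmed mean of M values moved the median log2 fold change of all genes by 0.16 for mir1180-3p, -0.24 for mir1271-5p, 0.40 for mir1301-3p, -0.19 for mir3613-5p, -0.12 for mir550-3p and -0.18 for mir124 Solid. DESeq2 size factors moved it by less than 0.1 in each of these comparisons.

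**Figure D1:**
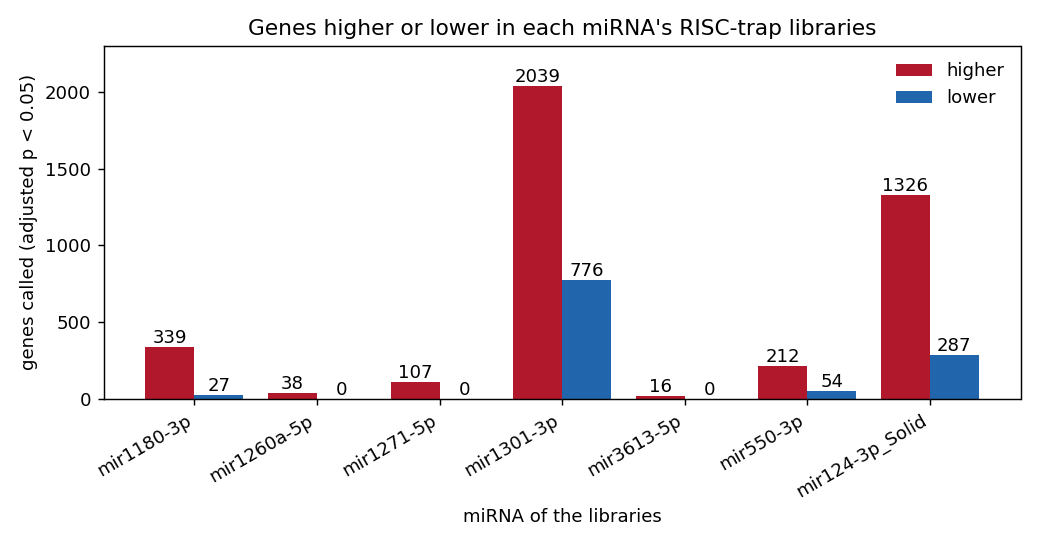
Bars give the number of genes called higher and lower at an adjusted p under 0.05 (edgeR) for each of the 7 comparisons. The bars for mir1301-3p reach 2039 higher and 776 lower, and those for mir3613-5p reach 16 and 0.

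In the mir1180-3p libraries RPL19, DCAF13 and HIST1H2BK led the named genes. RPL19 and RPS20 encode proteins of the large and the small ribosomal subunit, and RPL19 made up 5.26% of all counts in replicate 1 (95% Wilson interval 5.24% to 5.27%) and 4.92% in replicate 2 (4.91% to 4.93%). RPL19 averaged 53942 ± 4829 normalised CPM (SD, n = 2) against 2095 ± 616 in the other 10 libraries, a log2 fold change of 4.70 ± 0.25 (SE; adjusted p = 5.2e-09). RPS20 averaged 25841 ± 2586 CPM against 1652 ± 704 (log2 fold change 4.03 ± 0.27, adjusted p = 8.4e-08), and RPL14, also of the large subunit, averaged 9553 ± 428 against 987 ± 398 (3.30, adjusted p = 6.5e-06). DCAF13 and DNTTIP2, whose products act in the nucleolus where ribosomes are built, rose by 4.32 ± 0.24 (adjusted p = 7.1e-09) and 3.54 ± 0.28 (adjusted p = 5.9e-07) on the log2 scale. The histone mRNA HIST1H2BK (now H2BC12) rose by 4.18 ± 0.21 (adjusted p = 3.5e-09), from 102 ± 28.9 to 1801 ± 195 CPM. WEE1, the kinase that holds back entry into mitosis, rose by 2.51, from 416 ± 105 to 2356 ± 540 CPM (adjusted p = 1.1e-05).

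Other strong rises were COMMD8 with 3.57 ± 0.27 on the log2 scale and VSIG4, a complement receptor of macrophages, with 3.58 ± 0.38, although VSIG4 averaged only 43.1 ± 19.2 CPM. PTRF (now CAVIN1), which coats caveolae, stood at 43.7 CPM in replicate 1 and 328 CPM in replicate 2. Without replicate 2 its log2 fold change of 3.75 fell to 1.71 and was no longer called. The netrin receptor DCC had 7.18 and 65.3 CPM and a log2 fold change of 2.99, which was 0.72 and not called without replicate 2. The largest decreases were in SKAP1 (-2.57), TCEA3 (-2.41), TMEM180 (now SLC68A1; -2.13) and ZFPL1 (-1.97), each at no more than 5.09 CPM in these libraries. In this order they stood at -2.69, -2.23, -2.59 and -2.29 without replicate 1 of mir1180-3p and at -2.47, -2.60, -1.80 and -1.73 without replicate 2, and none of them was then called. The call also ended without replicate 2 of mir1301-3p for SKAP1 (-2.51) and TCEA3 (-2.33), without replicate 2 of mir3613-5p for SKAP1 (-2.40) and TCEA3 (-2.38), and without replicate 1 of mir550-3p for SKAP1 (-2.48), TCEA3 (-2.42) and ZFPL1 (-1.93). For TCEA3 it ended without replicate 2 of mir1271-5p (-2.34), replicate 1 of mir3613-5p (-2.32) and replicate 2 of mir550-3p (-2.39). TCEA3 also lost its call with the replicate number as a block (-2.40). SKAP1 and TCEA3 turned to 0.71 and 0.092 with mir124 Solid alone as the reference.

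By fixed gene list, 6 ribosomal protein genes rose and 1 fell among the 87 tested for mir1180-3p (7 and 1 adjusted over the list alone). The risers beyond those named were RPL4 (1.63), RPL13 (1.35) and RPL21 (1.21), and RPL7L1 fell by 1.47 on the log2 scale. The median of the list was -0.13 while the set test leaned up, and with upper-quartile scaling the median was 0.01. Of 499 zinc finger genes of the ZNF series 12 rose, led by ZNF230 (2.98), ZNF101 (2.47) and ZNF440 (1.85), also 12 when adjusted over the list alone. Of 49 histone genes 3 rose (4 adjusted over the list alone), with HIST1H2BE and HIST1H2BM beside HIST1H2BK. The cell-cycle lists had 2 risers each, RBL1 (2.60) and RRM2 (1.79) at the transition from G1 to S, and WEE1 and CDC20 (1.41) at that from G2 to M. In axon guidance DCC and DPYSL2 (1.58) rose (4 adjusted over the list alone), and among chromatin regulators MLL5 (now KMT2E; 1.14). RRM2 lost its call without replicate 1 (1.20), DPYSL2 without replicate 2 (1.46), and CDC20 and MLL5 without either replicate of mir1180-3p (1.42 and 1.16 without replicate 1, 1.40 and 1.11 without replicate 2). CDC20 turned to -1.32 with mir124 Solid alone as the reference.

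The edgeR test of mir1180-3p covered 17658 genes, of which 339 were higher and 27 lower, and the median log2 fold change of the higher genes was 1.90. An unadjusted p under 0.05 was reached by 2424 genes. As sets, none of the 18 lists tested by camera was called (adjusted p from 0.534 to 0.992). Leaving out replicate 1 of mir1180-3p left 172 genes called and leaving out replicate 2 left 170. Almost all of these calls were rises, so the decreases rested on both mir1180-3p libraries. DESeq2 called 492 genes higher and 201 lower.

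**Figure D2:**
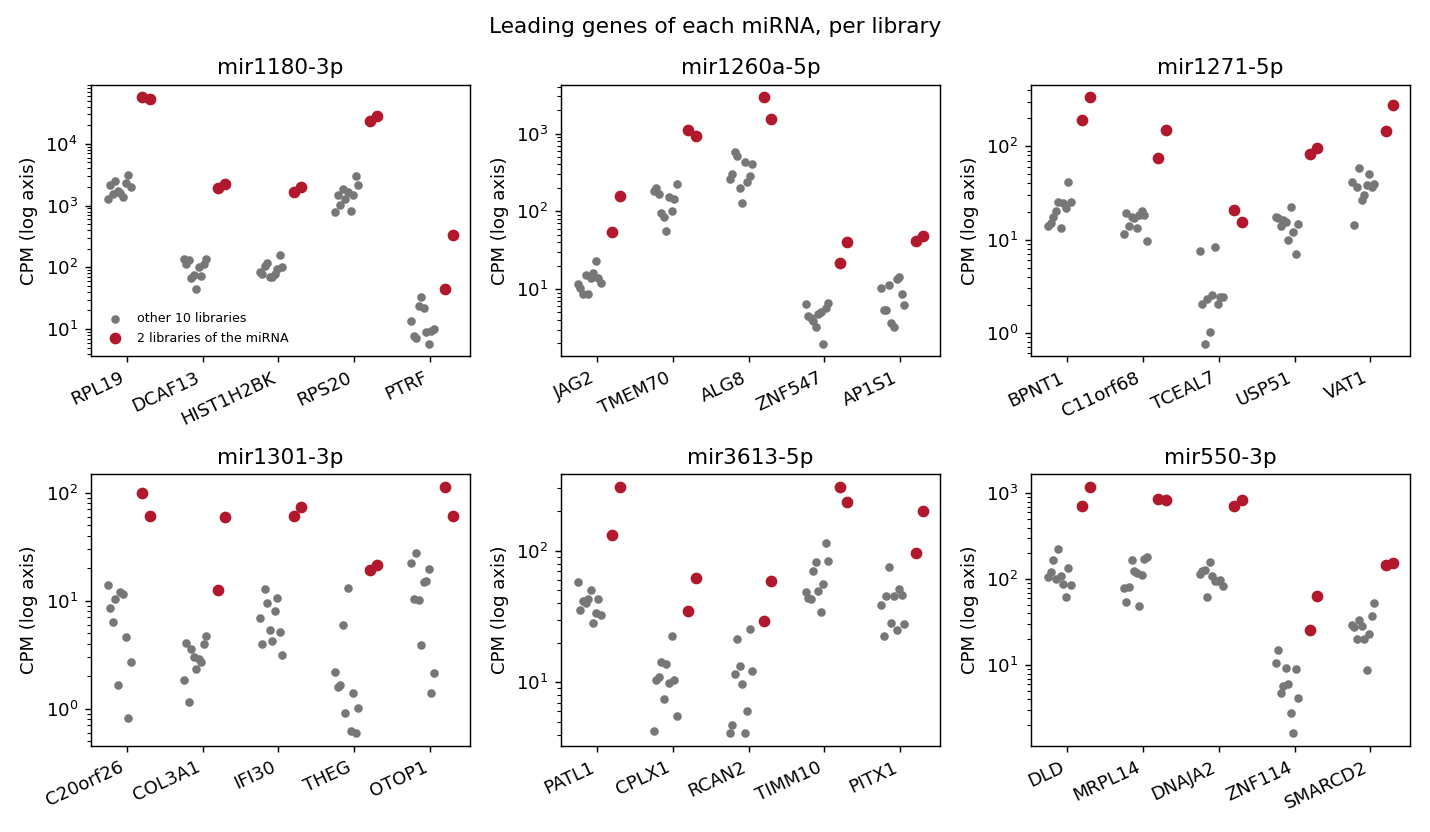
Each panel shows, for 1 miRNA, the normalised CPM on a log axis of the 5 genes with the largest increase in every library, red for its 2 libraries and grey for the other 10. RPL19 lies at 56981 and 52479 CPM in the mir1180-3p libraries and at no more than 3111 in the other 10.

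In the mir1260a-5p libraries the leading genes were JAG2, TMEM70 and ALG8. JAG2 encodes a ligand of the Notch receptors, TMEM70 helps assemble the mitochondrial ATP synthase, and ALG8 adds glucose to the sugar chains that are later attached to proteins. JAG2 rose by 3.03 ± 0.31 on the log2 scale (adjusted p = 8.9e-05), with 54.6 and 156 CPM in its libraries against a mean of 14.1 ± 4.95 in the other 10. TMEM70 averaged 1065 ± 91.3 CPM (SD, n = 2) against 146 ± 53.6, a log2 fold change of 2.94 ± 0.25 (adjusted p = 1.3e-05). ALG8 averaged 2312 ± 932 CPM against 357 ± 162 (2.81 ± 0.25, adjusted p = 2.0e-05). The clathrin adaptor subunit AP1S1 rose by 2.56 ± 0.31 and the GTPase DRG2 by 2.44 ± 0.24.

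Zinc finger genes rose too: ZNF547 (2.76), ZNF16 (2.54), ZNF350 (2.44), ZNF416 (2.03) and ZNF17 (1.98) were the 5 of 499 that rose in mir1260a-5p (12 adjusted over the list alone). Among chromatin regulators KDM6B, which removes methyl groups from histone H3, rose by 1.85 (adjusted p = 0.0233), and RPL36A (1.62) was the 1 ribosomal protein gene of 87 to rise (2 adjusted over the list alone). As a set the ribosomal protein genes leaned down, with a median log2 fold change of -0.23 (adjusted p = 9.9e-05, and adjusted p = 0.859 with an estimated correlation). The other 17 lists were not called (adjusted p from 0.274 to 0.939). Ribosomal protein genes took 6.42% of all counts in replicate 1 of mir1260a-5p and 11.92% in replicate 2. The other libraries outside mir1180-3p and mir124-3p lay between 6.75% and 11.87%. By this share the 2 mir1260a-5p libraries did not lean alike. ZNF547 was no longer called without replicate 2 of mir1260a-5p (2.18), ZNF350 without replicate 1 (2.23), RPL36A without replicate 2 (1.17) and KDM6B without either (2.06 without replicate 1, 1.54 without replicate 2). KDM6B also lost its call without replicate 2 of mir1180-3p (1.79), replicate 1 of mir550-3p (1.89) or replicate 2 of mir550-3p (1.82).

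For mir1260a-5p edgeR called 38 genes higher and 0 lower of 17658, where 941 had an unadjusted p under 0.05. DESeq2 called 60 higher and 12 lower. Without replicate 1 of mir1260a-5p 19 genes were called and 3 lists. AP1S1 turned to -0.25 with mir124 Solid alone as the reference.

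In the mir1271-5p libraries the largest rise was in BPNT1, whose product removes phosphate from sulfated nucleotides. BPNT1 averaged 285 ± 102 CPM (SD, n = 2) against 22.9 ± 8.97 in the other 10 libraries, a log2 fold change of 3.70 ± 0.26 (adjusted p = 6.9e-07). PRKACB, a catalytic subunit of protein kinase A, rose by 2.23 ± 0.24 (adjusted p = 0.00013), from 123.95 ± 69.6 to 524 ± 142 CPM. USP51, a histone deubiquitinase, rose by 2.69 ± 0.28 (adjusted p = 0.00012), and VAT1 by 2.57 ± 0.31. C11orf68 (2.88), TCEAL7 (2.73), FAM184A (2.54) and the mitochondrial enzyme gene OXSM (2.30) rose too. TCEAL7 was not called without replicate 1 of mir1271-5p (2.46) or without replicate 2 (2.96).

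Among 22 reported targets of mir96 and mir1271, which share a seed, 2 rose in the mir1271-5p libraries (3 adjusted over the list alone). REV1, a polymerase that copies damaged DNA, rose by 1.64 ± 0.23 (adjusted p = 0.0013), from 61.3 ± 12.6 to 189 ± 11.5 CPM. The adenylyl cyclase gene ADCY6 rose by 1.88 ± 0.35 (adjusted p = 0.0135), and was not called without replicate 2 of mir1271-5p (1.58). The median of the list was 0.31 (adjusted p = 0.00653, and adjusted p = 0.230 with an estimated correlation). With upper-quartile scaling the median was 0.08 and 1 target was called. The other 20 targets were not called.

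From the other lists, the ephrin ligand EFNB2 (1.61) and the Polycomb subunit SUZ12 (1.60) rose in mir1271-5p, as did RPS27 (1.59), CSNK1D (1.22), ZNF101 (1.76) and ZNF267 (1.52). Each lost its call without 1 of the mir1271-5p libraries: EFNB2 (1.52), RPS27 (0.74), CSNK1D (1.13) and ZNF267 (1.42) without replicate 2, and SUZ12 (1.18), CSNK1D (1.31) and ZNF101 (1.35) without replicate 1. RPS27 also lost it without replicate 2 of mir1180-3p (1.58) or replicate 1 of mir550-3p (1.55). CSNK1D lost it without replicate 1 or 2 of mir1180-3p (1.26 and 1.19) or of mir550-3p (1.27 and 1.18), and without replicate 1 of mir1260a-5p (1.17), mir1301-3p (1.17) or mir3613-5p (1.14). As sets, the G2/M genes (median 0.53, 0 of 30 called) and the reported mir124 targets (0.25, 0 of 57 called) leaned up, each at an adjusted p of 0.00653. Fibroblast and mesenchyme markers (-0.52, 0 of 12 called, adjusted p = 0.00653) leaned down. G1/S genes (0.28, 0 of 36 called and 1 adjusted over the list alone, adjusted p = 0.0247) and chromatin regulators (0.21, 1 of 59 called, adjusted p = 0.0205) leaned up, and axon guidance genes (-0.16, 1 of 46 called, adjusted p = 0.0384) down. With upper-quartile scaling the medians were 0.21 for the G2/M genes, 0.005 for the mir124 targets, 0.01 for the G1/S genes, -0.01 for the chromatin regulators, -0.41 for axon guidance and -0.80 for the fibroblast and mesenchyme markers. With an estimated correlation the adjusted p of these 6 lists lay between 0.414 for axon guidance and 0.657 for G2/M genes and chromatin regulators. The reference holds the mir1301-3p libraries, in whose own comparison the median of each of these lists had the opposite sign. It was 1.60 for the fibroblast and mesenchyme markers and -0.54 for the G2/M genes. With mir1301-3p left out, most of the lists called for mir1271-5p were no longer called.

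The edgeR test of mir1271-5p called 107 genes higher and 0 lower of 17658, where 1650 had an unadjusted p under 0.05. DESeq2 called 155 higher and 8 lower. The count rested on single libraries. Without replicate 1 of mir1271-5p 174 genes were called, of which 62 were among the 107, and no list was called. Without replicate 2 of mir1271-5p 35 genes were called. It was 71 without replicate 1 of mir1180-3p, 70 without replicate 2 of mir1180-3p, 69 without replicate 2 of mir3613-5p, 70 without replicate 1 of mir550-3p and 64 without replicate 2 of mir550-3p. The 11 lists that were not called had an adjusted p from 0.179 to 0.833.

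In the mir1301-3p libraries collagen mRNAs were among those that rose most. COL1A1, COL1A2 and COL3A1, which encode the fibrillar collagens of connective tissue, rose by 2.95 ± 0.37 (adjusted p = 0.00023), 3.10 ± 0.37 and 3.66 ± 0.43 (each adjusted p = 0.00015). Their levels stayed low, at 35.3 ± 20.5, 21.5 ± 13.9 and 39.3 ± 37.7 CPM (SD, n = 2) against 4.68, 2.79 and 3.17 in the other 10 libraries. COL3A1 stood at 12.5 CPM in replicate 1 and 59.5 in replicate 2, and without replicate 2 its log2 fold change was 2.02 and not called. IFI30, a thiol reductase of lysosomes, rose by 3.40 ± 0.28 (adjusted p = 7.4e-06) and C20orf26 (now CFAP61), a gene of motile cilia, by 3.69 ± 0.43 (adjusted p = 0.00015). QPRT, an enzyme of NAD synthesis, averaged 314 ± 149 CPM against 40.03 ± 15.8 (3.00 ± 0.33, adjusted p = 9.7e-05). The proton channel gene OTOP1 (3.15) and the testis gene THEG (now SPMAP2; 3.29) completed the leading genes.

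More abundant mRNAs rose too. SNAI2, a repressor that drives cells towards a mesenchymal state and a reported mir124 target, rose by 2.24 ± 0.24 (adjusted p = 7.6e-05) and averaged 989 ± 2.74 CPM in the mir1301-3p libraries against 229 ± 117. The histone methyltransferase gene MLL (now KMT2A) rose by 2.24 ± 0.24 (adjusted p = 6.6e-05), from 130 ± 29.5 to 604 ± 153 CPM. TCF4, a transcription factor of neural progenitors, rose by 1.93 ± 0.25 (adjusted p = 0.00035), from 62.1 ± 14.9 to 232 ± 88.0 CPM. The largest decreases were in ZNF134 (-2.60), ZNF114 (-2.31), the tyrosine sulfotransferase gene TPST2 (-2.18) and ITPA (-2.16), which clears inosine triphosphate. ZNF134 was no longer called without replicate 2 of mir1301-3p (-2.36), ITPA without replicate 1 (-1.79), and ZNF114 and TPST2 without either (-2.68 and -2.18 without replicate 1, -2.03 and -2.19 without replicate 2).

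Of 49 regulators of cortical progenitors and neurogenesis 8 rose and 0 fell in mir1301-3p (11 rose adjusted over the list alone), among them TCF4, MAP2 (1.64), SOX2 (1.51) and DCX (1.73). As a set they were not called (median 0.14, adjusted p = 0.166), and with upper-quartile scaling 19 rose, with a median of 0.54. Of 12 fibroblast and mesenchyme markers 7 rose (10 adjusted over the list alone), with LUM (2.40) and DCN (1.87) beside the collagens. Their median was 1.60 (adjusted p = 0.000253, and adjusted p = 0.508 with an estimated correlation). Of 9 blood markers 3 rose (4 adjusted over the list alone), led by HBD (2.53) and CD74 (1.47), with a median of 1.23 (adjusted p = 0.0232, and adjusted p = 0.508 with an estimated correlation). Their levels were low, as all 16 blood markers together summed to 26.4 and 29.5 CPM in the mir1301-3p libraries. Of 36 G1/S genes 6 fell and 0 rose (7 adjusted over the list alone), with RBL1 (-2.15), RRM2 (-1.46) and CCNE1 (-1.43) in front and a median of -0.67 (adjusted p = 0.000259, and adjusted p = 0.508 with an estimated correlation). With upper-quartile scaling 3 of the G1/S genes rose and 3 fell, with a median of -0.25. MAP2 was not called without replicate 1 (1.96) or replicate 2 (1.20) of mir1301-3p, SOX2 without replicate 2 (0.93). None of RBL1, RRM2 and CCNE1 was called without replicate 1 (-2.31, -1.42 and -1.72) or replicate 2 (-2.02, -1.52 and -1.20).

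Among the other lists of mir1301-3p, 4 leaned down at an estimated-correlation adjusted p of 0.521. These were the reported mir124 targets (2 of 57 rose and 3 fell, 2 and 2 adjusted over the list alone; median -0.48, adjusted p = 0.00165), the G2/M genes (2 of 30 fell, 0 adjusted over the list alone; -0.54, adjusted p = 0.00165), the chromatin regulators (3 of 59 rose and 6 fell, the same numbers adjusted over the list alone; -0.47, adjusted p = 0.00165) and the ZNF genes (36 of 499 rose and 32 fell, 33 and 30 adjusted over the list alone; -0.24, adjusted p = 0.0491). With upper-quartile scaling the balance turned: 5 reported mir124 targets rose and 0 fell (median -0.09), 1 G2/M gene rose and 0 fell (-0.13), 7 chromatin regulators rose and 3 fell (-0.08), and 74 ZNF genes rose and 19 fell (0.16). The histone genes were called as down by the set test (adjusted p = 0.0404, and adjusted p = 0.605 with an estimated correlation) while their median was 0.01 and their mean -0.16, with 5 of 49 lower (2 adjusted over the list alone) and a median of 0.37 with upper-quartile scaling.

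Single members of these lists rested on few libraries. The fall of CAPN2 (-0.99), CERS2 (-0.999), TOP2A (-1.10), CDC20 (-1.19), SMARCB1 (-1.76), HIST1H2BK (-1.36) and HIST1H1E (now H1-4; -1.82) in mir1301-3p was not called without replicate 1 of mir1301-3p, where they stood at -0.67, -1.15, -1.10, -0.99, -1.59, -1.30 and -1.33. They were not called without replicate 2 either, at -1.42, -0.88, -1.12, -1.44, -1.97, -1.45 and -2.60. The reference holds the mir1180-3p libraries, in which HIST1H2BK, RBL1, RRM2 and CDC20 were called higher. HIST1H2BK stood at 68.5 and 69.5 CPM in mir1301-3p, at 1652 and 2013 in mir1180-3p and between 77.8 and 157 in the other 8 libraries of the reference. HIST1H1C (now H1-2; -1.32) was not called without replicate 1 (-0.67). Leaving out replicate 1 of mir1180-3p ended the calls of CAPN2 (-0.98), CERS2 (-0.95), CDC20 (-1.20) and HIST1H1C (-1.39), and replicate 1 of mir550-3p those of CAPN2 (-1.01), CERS2 (-0.97), TOP2A (-1.10) and HIST1H1C (-1.38). Leaving out replicate 2 of mir550-3p ended those of CDC20 (-1.10) and HIST1H1C (-1.28), and replicate 2 of mir1180-3p that of HIST1H1C (-1.26). With mir124 Solid alone as the reference CAPN2 and TOP2A turned to 0.24 and 0.14. MLL2 (now KMT2D; 1.63), ZNF503 (1.54) and ZNF238 (now ZBTB18; 1.46) rose, and were not called without replicate 2 (1.32 for MLL2 and 1.28 for ZNF503) or replicate 1 (1.13 for ZNF238). MYRIP (2.24), the 1 of 22 reported mir96 and mir1271 targets to rise, was not called without replicate 1 (1.79).

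The lists of mir1301-3p that were not called as sets had an adjusted p from 0.0518 to 0.725. Of 87 ribosomal protein genes 13 rose and 2 fell, also 13 and 2 when adjusted over the list alone, with a median of -0.17 that turned to 0.22 with upper-quartile scaling and a mean of 0.00. RPL9 (1.14) and RPL10 (1.09) rose and RPL19 fell (-1.20), against a reference that holds the mir1180-3p libraries. In axon guidance 3 of 46 rose (1 adjusted over the list alone), which were SEMA5A (1.51), PLXNA3 (1.25) and NRP1 (0.99). In the RISC list LIN28A rose (1.53) and XPO5 fell (-1.31), of 26 tested. MFNG (1.98) rose in the Notch list, BTRC (0.91) in the Wnt list, SNAP25 (1.67) among neuron and glia markers and KRT5 (2.75) among liver and keratinocyte markers, and of 9 genes typical of HEK 293 0 were called. With upper-quartile scaling 23 ribosomal protein genes rose and 0 fell, 9 rose in axon guidance, 8 in the Notch list and 3 in the Wnt list, and 4 rose and 1 fell in the RISC list. RPL9 was not called without replicate 1 of mir1301-3p (0.65). The calls ended without replicate 1 and without replicate 2 for RPL10 (1.07 and 1.09), RPL19 (-1.20 and -1.22), SEMA5A (1.76 and 1.18), PLXNA3 (1.15 and 1.33), NRP1 (0.85 and 1.10), XPO5 (-1.38 and -1.26) and BTRC (0.80 and 0.99). Without replicate 1 of mir1180-3p RPL19 (-1.20), PLXNA3 (1.20), NRP1 (0.96) and BTRC (0.89) were not called, and without replicate 1 of mir550-3p RPL19 (-1.13), PLXNA3 (1.23) and NRP1 (0.95). Nor were PLXNA3 (1.25), NRP1 (1.004) and BTRC (0.80) without replicate 2 of mir550-3p, NRP1 (0.997) and BTRC (0.90) without replicate 2 of mir1180-3p, NRP1 (0.94) and BTRC (0.90) without replicate 2 of mir1260a-5p, or BTRC without replicate 1 of mir1260a-5p (0.92), mir1271-5p (0.87) or mir3613-5p (0.88). With mir124 Solid alone as the reference BTRC, PLXNA3 and RPL19 turned to -0.83, -0.057 and 0.63.

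The edgeR test of mir1301-3p called 2039 genes higher and 776 lower of 17658, so 72.4% of the calls were higher. The balance depended on the method: DESeq2 called 1356 higher and 1674 lower (44.8% higher), and upper-quartile scaling gave 4216 higher and 222 lower (94.998% higher). Without replicate 1 of mir1301-3p 114 genes were called and without replicate 2 142. The count was 1467 without replicate 1 of mir1180-3p, 1497 without replicate 1 of mir550-3p and 4509 without replicate 2 of mir1271-5p. Of the lists, 5 in place of 8 were called without replicate 1 of mir1271-5p or without replicate 2 of mir550-3p.

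**Figure D3:**
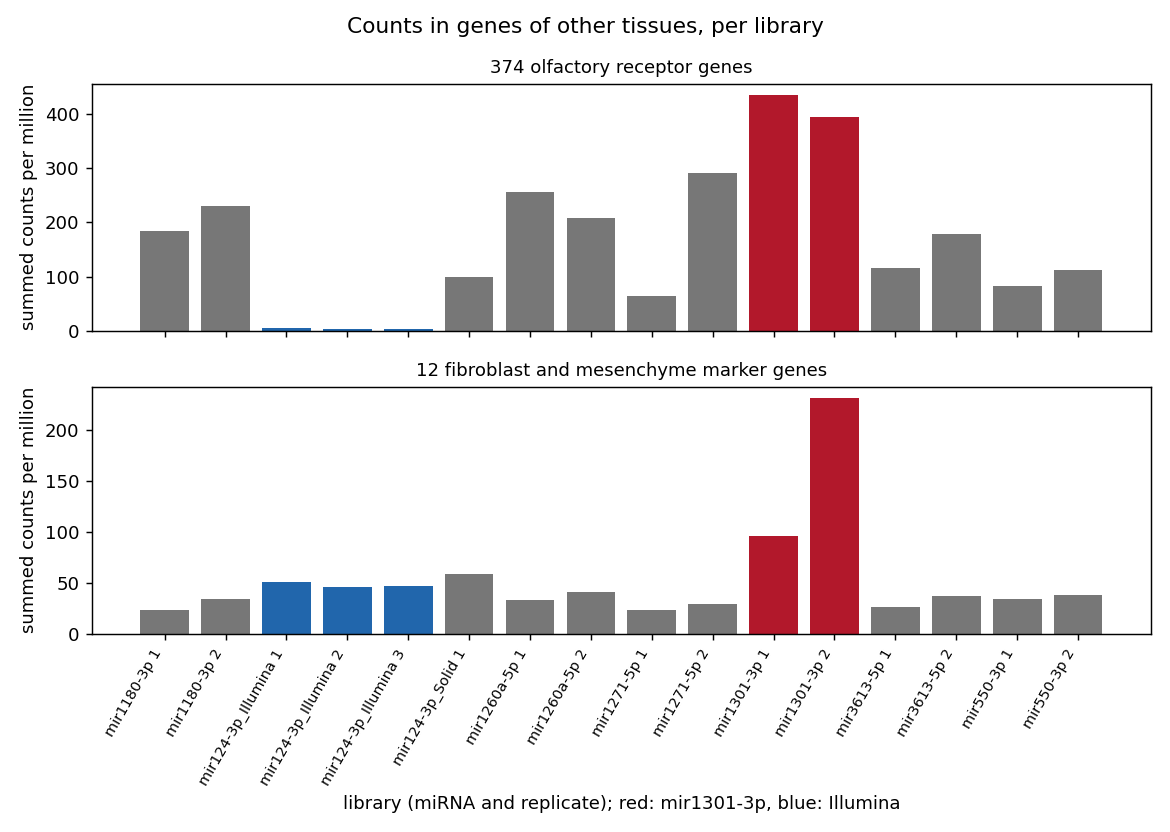
Bars give, for each library, the summed CPM of 374 olfactory receptor genes and of 12 fibroblast and mesenchyme marker genes, red for mir1301-3p and blue for the Illumina libraries. The mir1301-3p libraries reach 433 and 394 for the olfactory receptor genes and 95.9 and 231 for the markers.

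Olfactory receptor genes, which serve the sensory neurons of the nose, were counted in every library. The 374 genes summed to 433 CPM in replicate 1 of mir1301-3p (95% Wilson interval 419 to 449) and 394 in replicate 2 (381 to 408). The other libraries not titled as Illumina lay between 64.2 (60.6 to 68.0) in replicate 1 of mir1271-5p and 291 (280 to 303) in its replicate 2. In the Illumina libraries the sum was 5.29 (4.36 to 6.41), 3.17 (2.49 to 4.05) and 3.62 (2.96 to 4.42). The fibroblast and mesenchyme markers summed to 95.9 (89.2 to 103) and 231 (221 to 241) CPM in the mir1301-3p libraries, and in the other libraries not titled as Illumina to between 23.3 (20.9 to 26.1) and 58.3 (54.3 to 62.7).

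In the mir3613-5p libraries PATL1 led the named genes. PATL1 is a scaffold of the complex that removes the cap from mRNAs, PLAGL1 is an imprinted zinc finger regulator of growth, and TIMM10 carries proteins into mitochondria. PLAGL1 averaged 1227 ± 54.2 CPM (SD, n = 2) against 355 ± 174 in the other 10 libraries, a log2 fold change of 1.91 ± 0.22 (adjusted p = 0.0008), and kept its call without any single library. PATL1 rose by 2.54 ± 0.27 (adjusted p = 0.00059) with 133 and 307 CPM against a mean of 42.3 ± 9.46, and was not called without replicate 2 of mir3613-5p (1.83). TIMM10 rose by 2.27 ± 0.28 (adjusted p = 0.0013), from 65.8 to 303 ± 66.6 CPM, and was not called without replicate 1 (2.02). The synaptic gene CPLX1 (2.29), the calcineurin regulator RCAN2 (2.28) and the hindlimb factor PITX1 (1.999) were not called without replicate 2 (1.83, 1.73 and 1.40), NUDT16L1 (1.92) without replicate 1 (1.73) and NDRG4 (1.83) without either (1.51 and 2.06). PITX1 also lost its call without replicate 2 of mir1180-3p (1.93) or of mir550-3p (1.93), and NDRG4 without replicate 2 of mir1180-3p (1.80). NUDT16L1 stood at 248 and 206 CPM in the mir3613-5p libraries and was nearly as high in those of mir1271-5p, at 194 and 201 CPM.

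For mir3613-5p edgeR called 16 genes higher and 0 lower of 17658, where 2481 had an unadjusted p under 0.05. DESeq2 called 104 higher and 38 lower. Without replicate 1 of mir3613-5p 8 genes were called. The count was 9 without replicate 2 of mir1180-3p, 38 without replicate 2 of mir1260a-5p, 27 without replicate 2 of mir1271-5p, 39 without replicate 2 of mir1301-3p and 9 without replicate 2 of mir550-3p. Without replicate 2 of mir3613-5p 11 were called, of which 4 were among the 16.

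None of the list members was called in mir3613-5p. As sets, the reported mir124 targets (median 0.28), the G1/S genes (0.19), the Wnt genes (0.23, with 1 higher adjusted over the list alone) and the chromatin regulators (0.20) leaned up and the fibroblast and mesenchyme markers (-0.57) down. Each had an adjusted p of 0.0271, and adjusted p = 0.773 with an estimated correlation. With upper-quartile scaling the medians in this order were 0.06, 0.01, 0.06, 0.02 and -0.76. In the comparison of mir1301-3p, whose libraries are in the reference, they were -0.48, -0.67, -0.32, -0.47 and 1.60. With mir1301-3p left out, no list was called for mir3613-5p. Of these 5 lists 0 were called without replicate 2 of mir1260a-5p or replicate 2 of mir1271-5p, and 3 lists without replicate 1 of mir3613-5p. The other 13 lists had an adjusted p from 0.0852 to 0.9999.

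In the mir550-3p libraries DLD and MRPL14 led the named genes. DLD is a subunit shared by the dehydrogenase complexes that feed the citric acid cycle, MRPL14 belongs to the mitochondrial ribosome, and DNAJA2 and CCT4 help other proteins fold. DLD averaged 977 ± 294 CPM (SD, n = 2) against 128 ± 53.2 in the other 10 libraries, a log2 fold change of 2.99 ± 0.27 (adjusted p = 1.8e-05). MRPL14 averaged 869.6 ± 58.4 CPM against 123 ± 56.7 (2.92 ± 0.28, adjusted p = 3.7e-05), and DNAJA2 802 ± 42.1 against 113 ± 28.3 (2.84 ± 0.24, adjusted p = 1.2e-05). CCT4 rose by 2.41 ± 0.33 (adjusted p = 0.0015) and SPRY2, an inhibitor of growth factor signalling, by 2.39 ± 0.34 (adjusted p = 0.0018). SMARCD2, a subunit of the SWI/SNF remodeller, rose by 2.45 ± 0.30 (adjusted p = 0.00059), from 30.1 ± 13.3 to 156 ± 1.49 CPM. ZNF114 (2.84) and TBXAS1 (2.40) rose too. Without replicate 2 of mir550-3p CCT4 (2.04), SPRY2 (1.999), ZNF114 (2.13) and TBXAS1 (1.65) were not called.

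Among the largest decreases of mir550-3p, the defensin gene DEFB123 fell by 5.92 on the log2 scale (SE 0.83, adjusted p = 0.0017), from 9.04 ± 6.15 to 0.106 ± 0.0382 CPM. TPRX1 (-4.46), a homeobox gene of the early embryo, SLC46A2 (-4.40), a transporter of the thymus, and the endothelin gene EDN2 (-4.34) fell as well, from 19.0 ± 11.7, 67.8 ± 33.1 and 16.8 ± 15.5 CPM. In the order DEFB123, TPRX1, SLC46A2, EDN2 the values were -5.65, -4.38, -4.70 and -4.46 without replicate 1 of mir550-3p and -6.32, -4.54, -4.14 and -4.21 without replicate 2, none of them called. SLC46A2 also lost its call with a block for odd or even numbers (-4.28), and without replicate 1 (-4.38) or replicate 2 (-4.40) of mir1260a-5p, replicate 1 (-4.48) or replicate 2 (-4.27) of mir1301-3p, and replicate 2 of mir3613-5p (-4.38). With mir124 Solid alone as the reference SMARCD2, DEFB123, TPRX1 and SLC46A2 turned to -0.047, 0.43, 0.70 and 0.29.

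Among the lists of mir550-3p, the ribosomal protein genes leaned up, with 2 of 87 called higher (8 adjusted over the list alone), a median of 0.31 and an adjusted p of 0.00021 (adjusted p = 0.703 with an estimated correlation). The 2 were RPL3L (1.83) and RPL22L1 (1.005), and with upper-quartile scaling 0 were called and the median was 0.17. DGCR8, which is part of the complex that cuts miRNA precursors in the nucleus, fell by 1.502 (adjusted p = 0.0273). It was the 1 called of 26 RISC genes (2 higher and 3 lower adjusted over the list alone). Of 499 ZNF genes 10 rose and 2 fell (10 and 4 adjusted over the list alone), with ZNF273 (1.61) and ZNF410 (1.42) beside ZNF114. With upper-quartile scaling 6 ZNF genes rose and 3 fell, and 3 RISC genes fell. SMARCD2 was the 1 called of 59 chromatin regulators (1 and 1 adjusted over the list alone), and of the histone genes 0 were called (4 higher adjusted over the list alone). The other 17 lists had an adjusted p from 0.0608 to 0.839. DGCR8 (-1.76 and -1.28), RPL22L1 (0.70 and 1.26), ZNF273 (1.53 and 1.68) and ZNF410 (1.46 and 1.38) were not called without replicate 1 or replicate 2 of mir550-3p. DGCR8 was not called without replicate 2 of mir1180-3p (-1.44). RPL22L1 was not called without replicate 1 or 2 of mir1180-3p (1.02 and 0.99), mir1301-3p (1.03 and 0.98) or mir3613-5p (1.01 and 0.99), or without replicate 1 of mir1260a-5p (0.99).

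For mir550-3p edgeR called 212 genes higher and 54 lower of 17658, and 2898 had an unadjusted p under 0.05. DESeq2 called 542 higher and 338 lower. With either mir550-3p library left out, every gene that edgeR called was a rise. Without replicate 1 of mir550-3p 32 genes were called and without replicate 2 9. The count was 152 without replicate 2 of mir1180-3p, 616 without replicate 1 of mir1271-5p and 172 without replicate 2 of mir3613-5p. A further list was called, 2 in all, without replicate 2 of mir1180-3p, mir1260a-5p, mir1301-3p or mir3613-5p, or without replicate 1 of mir550-3p.

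The miRNA mir124-3p is abundant in neurons, and many of its targets have been reported. Its library was therefore used to ask whether reported targets were higher than in the other pulldowns. RHOG, a small GTPase and a reported target, had the largest rise, with 596 CPM in the mir124 Solid library against 20.7 ± 10.5 in the other 12 (log2 fold change 4.91 ± 0.35, adjusted p = 4.5e-07). PLOD3, an enzyme of collagen processing, rose by 3.43 ± 0.34 (adjusted p = 1.4e-05) and the ceramide synthase gene CERS2 by 2.65 ± 0.27 (adjusted p = 1.5e-05), to 1097 CPM from 183 ± 56.2. PTBP1, the splicing repressor that neurons switch off, rose by 2.38 ± 0.30 (adjusted p = 0.0001), to 756 CPM from 152 ± 51.9. VAMP3 (2.19), TMEM109 (2.15), MAPK14 (2.19), CTDSP1 (2.50), LRRC1 (2.51) and NEK6 (2.28) rose as well, each at an adjusted p under 0.0003 and each in every alternative in which it was tested. The spread of the lone library was taken from the other groups.

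Of 57 reported mir124 targets 23 rose and 1 fell in the mir124 Solid library (25 and 4 adjusted over the list alone), with a median of 0.69 (adjusted p = 2.5e-06, and adjusted p = 0.452 with an estimated correlation). The one that fell was ROCK1 (-1.64, adjusted p = 0.0446). Against the same 12 libraries, the 3 Illumina libraries had 35 targets higher and 9 lower. All 23 that rose on SOLiD also rose on Illumina, RHOG by 5.18, PLOD3 by 3.74, CERS2 by 2.81 and PTBP1 by 2.26. CTNND1 (2.92 on Illumina, 0.05 on SOLiD) and ITGB1 (2.28 and 0.57) differed most in the other direction and were chosen here after their values were seen. Because both mir124 contrasts share a reference, the platforms were also compared with the reference split. With mir124 Solid set against replicate 1 of each miRNA and Illumina against replicate 2, 36 targets were up in both, 12 down in both and 9 opposite. With the split exchanged the counts were 38, 14 and 5. Over all genes, 360 of the 369 called higher on SOLiD against the replicate 1 libraries were higher on Illumina. If the calls were unrelated, 90.1 would be expected. Both sides of the split hold the same other miRNAs, so any other difference between the mir124 libraries and those pulldowns enters both contrasts. The share of TNRC6A was 5.11% in mir124 Solid and 4.003%, 1.07% and 3.97% on Illumina, against at most 1.49% in the 12. Neither the overlap nor the target counts of the split can part recovery by mir124 from such a difference. In mir124 Solid the median log2 fold change was 0.69 for the reported targets, 0.91 for the G1/S genes and -0.12 over all genes.

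**Figure D4:**
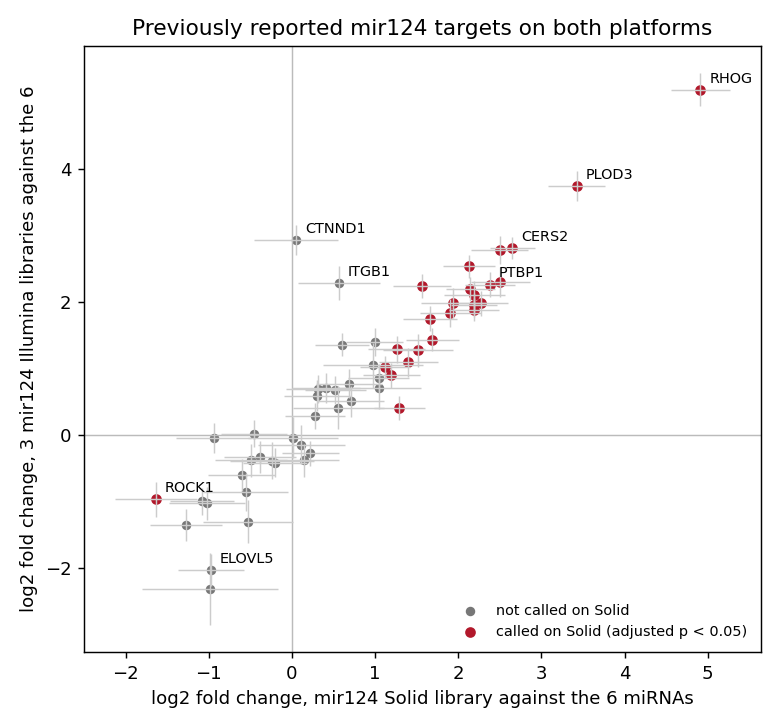
Each point is 1 of 57 reported mir124 targets, with its log2 fold change against the 6 other miRNAs in the mir124 Solid library on the x axis and in the 3 Illumina libraries on the y axis, grey lines for the SE and red for targets called on SOLiD. RHOG lies at 4.91 and 5.18, and CTNND1 at 0.05 and 2.92.

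Beyond the reported targets, ERAL1, which handles mitochondrial ribosomal RNA, rose by 4.40 ± 0.32 in mir124 Solid (adjusted p = 4.5e-07) and the fatty acid elongase gene ELOVL1 by 4.18 ± 0.26 (adjusted p = 8.8e-08), to 409 CPM from 22.8 ± 4.06. The cytokine gene LIF (3.74), TGDS (3.67) and SCAMP2 (3.66) rose likewise. GGTLC1 (4.19) and LRIT2 (3.88) rose on SOLiD and had counts of 0 in each Illumina library. The largest decreases were in DEFB123 (-5.37), TPRX1 (-4.41), ZNF83 (-3.31) and FAM72A (-3.05), which has near-identical copies in the genome. FAM72A was not called without replicate 1 (-2.89) or 2 (-3.04) of mir1180-3p, replicate 1 of mir1301-3p (-2.93), replicate 2 of mir3613-5p (-2.95) or replicate 1 (-3.07) or 2 (-3.01) of mir550-3p, and turned to 0.24 with the Illumina libraries.

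In mir124 Solid 14 of 36 G1/S genes were higher and 0 lower (18 adjusted over the list alone), and 22 were not called. Those higher included CCNE1 (2.84), MCM2 (2.57), MCM3 (2.30) and E2F1 (1.90). The median of the 36 was 0.91 (adjusted p = 6.4e-06, and adjusted p = 0.452 with an estimated correlation). Of 88 ribosomal protein genes 2 rose and 5 fell (1 and 5 adjusted over the list alone), with RPS14 (1.71) up and RPL27 (-1.83) and RPS20 (-1.89) down and a median of -0.41 (adjusted p = 0.0287, and adjusted p = 0.936 with an estimated correlation). The other 15 lists were not called (adjusted p from 0.0553 to 0.932). In the RISC list 7 of 26 rose and 1 fell (7 and 3 adjusted over the list alone), with TNRC6A (2.35) and DROSHA (1.86) up and DCP2 (-1.66) down. The median of this list was -0.04 and its mean 0.16. The counts of TNRC6A do not separate the endogenous gene from the GW182 construct. List members in this paragraph and the next were named after their values were seen.

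In the Notch list 4 rose and 0 fell (5 and 1 adjusted over the list alone), led by MAML1 (2.48) and NCSTN (2.46), and in the Wnt list 4 rose, led by DVL2 (2.54). In axon guidance 4 rose, led by PLXNB2 (2.47) and EFNA1 (2.34). Of 59 chromatin regulators 6 rose and 2 fell (9 and 4 adjusted over the list alone), with SMARCD2 (2.09) and HDAC1 (1.55) up and SUZ12 (-1.81) down. Of 30 G2/M genes 3 rose and 1 fell (6 and 3 adjusted over the list alone), with CDC20 (2.49) and AURKA (2.07) up and TTK (-2.14) down. Of 50 regulators of cortical progenitors 0 rose and 3 fell, which were ASPM (-2.59), HMGA2 (-1.93) and SOX4 (-1.37). Of 504 ZNF genes 37 rose and 8 fell (39 and 9 adjusted over the list alone), and of 55 histone genes 3 rose and 2 fell. MTOR (1.53) was the 1 called among reported mir96 and mir1271 targets, ACTA2 (2.71) among fibroblast and mesenchyme markers and SLC1A3 (2.19) among neuron and glia markers, and none was called among the blood, liver and keratinocyte, or HEK 293 genes. With upper-quartile scaling the balance for mir124 Solid moved down: 21 reported targets rose and 3 fell (median 0.51), 13 and 0 of the G1/S genes (0.73), 3 and 4 of the G2/M genes, 30 and 20 of the ZNF genes, 0 and 7 of the cortical regulators, 1 and 7 of the ribosomal protein genes, 6 and 4 of the chromatin regulators, 6 and 3 of the RISC genes, 1 and 2 of the histone genes, 4 and 1 in the Notch list, 3 and 0 in the Wnt list and 2 and 1 in axon guidance.

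The edgeR test of mir124 Solid against the 6 covered 18135 genes, of which 1326 were higher and 287 lower, with a median log2 fold change of 1.72 among the higher. With the 3 Illumina libraries in place of the Solid library 4370 were higher and 7937 lower, and GGTLC1 and LRIT2 turned direction there. The balance for the Solid library depended on scaling, and with upper-quartile scaling a smaller share of its calls was higher. DESeq2 called 1833 higher and 845 lower.

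The last comparison set the 3 Illumina libraries of mir124 against the Solid library, which compares 1 miRNA across platforms and cannot part the platform from library preparation, alignment or counting. The annotation and counting behind each platform are not given in the sources used here, so a count of 0 in every library of 1 platform is not shown to be an absence of the mRNA. INS, the insulin gene, had 4944 counts over the 3 Illumina libraries and 0 on SOLiD, at least 237-fold higher in each Illumina library against a limit of 3 counts per library. MIA, INS-IGF2 (which shares its reads with INS) and HEATR8 (now MROH7) averaged 89.2 ± 18.7, 90.6 ± 20.8 and 141 ± 17.8 CPM (SD, n = 3) on Illumina against 0.317, 0.555 and 0.872. In the other direction MIF, a cytokine abundant in most cell lines, had 9138 counts on SOLiD and 0 in each Illumina library, at least 4763-fold lower. LUC7L2 (an entry whose transcript is now listed under FMC1-LUC7L2), ATP5E (now ATP5F1E) and LUZP6 were also at 0 on Illumina, with 250.0, 223.9 and 175.5 CPM on SOLiD. The edgeR test covered 18271 genes, of which 433 were higher on Illumina and 3563 lower. Between 3305 and 3687 genes had a count of 0 in an Illumina library, and between 296 and 769 in any of the other libraries, so in this the 12 were like mir124 Solid. The lone Solid library was again taken to vary like the other groups, and the count with a floor of 5 CPM in 2 libraries was 401 higher and 1122 lower.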

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

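The odd or even block, the thinning to the smallest total, the filter at a mean of 20 CPM and the removal of mir1301-3p were chosen after seeing the data; the other alternatives were set before. The cause was not tested where a count moved, except where fewer genes or libraries entered. Of the values of named genes under all alternatives, 3231 kept their direction and call, 305 kept their direction and lost the call, and 16 turned.

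With DESeq2 the counts of called genes were 693 for mir1180-3p (71.0% higher against 92.6% in edgeR), 72 for mir1260a-5p, 163 for mir1271-5p, 142 for mir3613-5p (73.2% higher), 880 for mir550-3p (61.6% higher against 79.7%) and 2678 for mir124 Solid. With upper-quartile scaling they were 50 for mir1271-5p, 4438 for mir1301-3p and 9 for mir3613-5p, and the share higher for mir124 Solid was 60.02% against 82.2%. A filter of 5 CPM in 2 libraries tested fewer genes and gave 1330 for mir1301-3p, 10 for mir3613-5p and 1523 for the platforms. A mean of at least 20 CPM gave 45 for mir1271-5p, 453 for mir1301-3p (89.2% higher against 72.4%) and 7 for mir3613-5p.

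Against mir124 Solid alone the counts were 1480 for mir1180-3p, 335 for mir1260a-5p, 450 for mir1271-5p, 189 for mir3613-5p and 491 for mir550-3p, and most were lower, with 21.2% higher for mir1180-3p and 22.8% for mir1301-3p. With mir124 Solid added to the reference mir3613-5p had 28. Against miRNAs whose descriptions share a naming style there were 20 for mir1260a-5p, 37 for mir1271-5p, 7 for mir3613-5p and 4209 for mir550-3p, which is then set against mir1301-3p alone; the lists called were 3, 2, 0 and 8. With mir1301-3p left out mir550-3p had 123, and the lists called were 2 for mir1260a-5p, 1 for mir1271-5p, 0 for mir3613-5p and 3 for mir550-3p. With all 16 libraries in the fit the counts were 675 for mir1180-3p, 64 for mir1260a-5p, 27 for mir3613-5p and 809 for mir550-3p. The Illumina libraries in place of mir124 Solid gave 12307.

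With the replicate number as a block the counts were 408 for mir1180-3p, 42 for mir1260a-5p, 94 for mir1271-5p, 3738 for mir1301-3p, 12 for mir3613-5p and 313 for mir550-3p, each within 1.5 times the count without the block. A block for odd or even numbers in the descriptions gave 621 for mir1180-3p, 66 for mir1260a-5p, 207 for mir1271-5p, 4796 for mir1301-3p, 113 for mir3613-5p and 936 for mir550-3p. Of the named genes TCEA3 in mir1180-3p lost its call with the replicate block (-2.40, adjusted p = 0.0658) and SLC46A2 in mir550-3p with the odd or even block (-4.28, adjusted p = 0.0549). With an estimated correlation 0 lists were called for mir1260a-5p, mir1271-5p, mir1301-3p, mir3613-5p, mir550-3p and mir124 Solid.

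Leaving out 1 library in turn, the counts ranged from 170 to 438 for mir1180-3p, 19 to 50 for mir1260a-5p, 35 to 174 for mir1271-5p, 114 to 4509 for mir1301-3p, 8 to 39 for mir3613-5p, 9 to 616 for mir550-3p, 1257 to 1945 for mir124 Solid and 3024 to 3449 for the platforms. The lists called ranged from 0 to 0, 1 to 3, 0 to 10, 5 to 9, 0 to 5, 1 to 2 and 2 to 4 for mir1180-3p, mir1260a-5p, mir1271-5p, mir1301-3p, mir3613-5p, mir550-3p and mir124 Solid. The libraries that moved the total of called genes or the number of called lists by over 1.5 times are named in the report. The numbers higher and lower were not held to this bound separately.

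Values that turned against mir124 Solid alone were SKAP1 (0.71), TCEA3 (0.092) and CDC20 (-1.32) in mir1180-3p, AP1S1 (-0.25) in mir1260a-5p, CAPN2 (0.24), TOP2A (0.14), BTRC (-0.83), PLXNA3 (-0.057) and RPL19 (0.63) in mir1301-3p, and SMARCD2 (-0.047), DEFB123 (0.43), TPRX1 (0.70) and SLC46A2 (0.29) in mir550-3p. With the Illumina libraries in place of mir124 Solid, GGTLC1 (-7.97), LRIT2 (-8.46) and FAM72A (0.24) turned, where GGTLC1 and LRIT2 had counts of 0 on Illumina, so that their fitted values are no bounds. The cause was not tested.

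No filter, DESeq2 size factors, a minimum fold of 2 and thinning to the smallest total kept the count of every miRNA comparison in which they were run within 1.5 times. The count of libraries closest to their own partner, 5 of 12, was 6 with the filters at 5 CPM and at a mean of 20 CPM. The alternatives for seed sites were not run. On simulated data between 3% and 34% of 2-fold changes were recovered.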

Other observations

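Tests of the ribosomal protein genes, of odd and even numbers and of the genes above the other libraries in exchanged pairs were chosen only after their results were seen; the other tests were chosen before.

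DEFB123, TPRX1 and SLC46A2, genes of the epididymis, the early embryo and the thymus, were low in the same libraries. DEFB123 stood at 0.07 and 0.13 CPM in the mir550-3p libraries, 0.08 in mir124 Solid and 0 in the Illumina libraries. In the other libraries not titled as Illumina it lay between 1.02 CPM in replicate 2 of mir1180-3p and 18.7 CPM in replicate 2 of mir1301-3p. SLC46A2 stood at 3.47 and 2.55 CPM in mir550-3p, 2.62 in mir124 Solid and 4.97 in replicate 2 of mir1180-3p, against 85.8 in replicate 1 of mir1180-3p. TPRX1 stood at 0.66 and 0.80 CPM in mir550-3p, 0.48 in mir124 Solid and 2.37 in replicate 2 of mir1180-3p. All were chosen after their values were seen.

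RPL19, RPS20 and RPL14 rose strongly in the mir1180-3p libraries. A general rise of ribosomal protein mRNAs is argued against, since the other 84 tested had a median log2 fold change of -0.15 with quartiles of -0.44 and 0.12. A single library as the source is also argued against, since with either mir1180-3p library left out all 3 genes stayed called, with a log2 fold change of at least 3.25. Recovery by mir1180-3p itself, which the design names, may explain the rise and was not tested, since no transcript sequence was used here.

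In the mir1301-3p libraries 2039 genes rose, and a higher background of reads over all genes stays open. Of these genes 13.9% gained over 20 times the median gain of the olfactory receptor genes, which was 0.604 CPM. This share cannot decide the question, because genes at low counts could hardly gain so much. The median gain of the 2039 genes was 2.49 CPM. The olfactory receptor genes themselves had a median log2 fold change of 1.499. For the other miRNAs this median lay between -0.65 for mir550-3p and 0.46 for mir1180-3p. For the 200 called genes with at least 20 CPM in the other libraries a background stays open too. Their median gain was 96.0 CPM and the largest gain of an olfactory receptor gene was 8.64. The bound set before the test was wrong, because a call from 20 CPM already took a gain of at least 16.2 CPM. Lower depth is argued against by the 1789 genes called higher after thinning. The naming style shared with mir550-3p is argued against by the genes called higher against the 4 other miRNAs. They had a median log2 fold change of 1.79 against mir550-3p. The same mir1301-3p libraries entered the choice of these genes, so the size of this value can be inflated. The mir550-3p libraries were not set against the 4 other miRNAs for these genes. RNA from other cells stays open for the fibroblast and mesenchyme markers. Their median of 1.60 was near that of the olfactory receptor genes, and their most abundant gene, COL3A1, averaged 39.3 CPM. The 2 sets moved apart between the mir1301-3p libraries. From replicate 1 to replicate 2 the markers went from 95.9 to 231 CPM and the olfactory receptor genes from 433 to 394. Recovery by mir1301-3p itself was not tested.

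Libraries of the 4 miRNAs described by sample numbers resembled libraries of other miRNAs. An exchange of labels between a pair of libraries is argued against by genes in which both libraries of a pair lay over 1 log2 unit above the other 10. The 2 libraries of a miRNA had between 14 and 88 such genes, and 3 for mir3613-5p, while the 60 pairs of different miRNAs had at most 4. Over 30 exchanges the 2 new pairs had at most 35.3% as many as the 2 old ones, and 3 against 24 for replicate 2 of mir1271-5p exchanged with replicate 1 of mir3613-5p. Correlations alone leave it open. In 0 of the 30 exchanges did both new pairs correlate better than both old ones and over 0.1, as the test written before asked. But the largest advantage of the lower new correlation over the higher old one was 0.195, for replicate 2 of mir1260a-5p exchanged with replicate 1 of mir1271-5p (0.0753 and 0.0891 in place of -0.119 and -0.129), where 2 genes stood against 35. The exchange of mir1271-5p and mir3613-5p libraries gave 0.384 and 0.123 in place of -0.129 and 0.178. That bound was too strict, because libraries of 1 miRNA themselves correlated at between -0.129 and 0.603. A wrong label in mir3613-5p from outside these libraries was not tested. An effect tied to odd and even sample numbers stays open: the differences between the odd and the even library correlated at between 0.0853 and 0.365 over the 6 pairs of miRNAs, with 4 of the 6 over 0.1. Differences between replicate 1 and replicate 2 correlated at between 0.196 and 0.365 over the 6 pairs among mir1260a-5p, mir1271-5p, mir1301-3p and mir3613-5p. The 9 pairs with mir1180-3p or mir550-3p lay between -0.142 and 0.0737, so batches shared by replicate number stay open, with values that go with them in those 4 miRNAs. For mir1260a-5p, mir1271-5p and mir3613-5p replicate 1 is the library with the odd number. Among these the correlations by odd or even number and by replicate number are the same values and not separate evidence. A block for odd or even numbers gave 113 genes in place of 16 for mir3613-5p. It gave 936 in place of 266 for mir550-3p, whose libraries have no sample number. What such a number stood for in the laboratory is not given in the sources used here. A biological difference between these libraries of 1 miRNA was not tested.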
